A study of Macaca mulatta with 22 samples.

How the data were processed

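Per the labels, livers and lungs were digested with DNase I and collagenase, leukocytes were taken from a Percoll gradient, and, per the series design text, live CD45+ CD3+ cells negative for CD14 and CD20 were sorted from cryopreserved samples. Libraries were made with 10x Genomics 5' v2 chemistry, with macaque primers for the TCR. Per the file headers, the deposited counts are whole-number UMI counts per gene and cell barcode from Cell Ranger 7.0.0, and per the series design text they come from its multi and aggregate pipelines with a filtered Ensembl annotation of the rhesus macaque. Aligner options are not given in the sources used here, and no genome was used. The deposited TCR tables give the number of cells per clonotype with its CDR3 sequences. They hold no cell barcodes, so clonotypes were not joined to expression, and the version that made them is not given in the sources used here. TCR tables of lung R230 and lung R233 were not used here. A deposited batch name places livers R227, R276 and R312 in batch 1 and all other libraries, every lung included, in batch 2, without stating what defines a batch.

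The gene list has 22387 features and is identical in the 11 libraries. Of these, 5066 carry no symbol in the file, 400 of them were given one from a table of gene IDs and symbols, and 38 share a symbol with another feature. A pair of unnamed IDs holds 12.3% of all UMIs, and 2.53% to 28.2% of the T-cell UMIs of a library among those compared. Log2 CPM profiles of the 10 libraries compared correlated at 0.782 to 0.969 over their 45 pairs, and 0 pairs were identical.

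Barcodes were kept with at least 300 detected genes and at most 10% mitochondrial UMIs. Barcodes with fewer genes were 20.7%, 62.2% and 25.9% in livers R230, R232 and R235, and 0.157% to 9.40% in the other libraries compared. Barcodes with more mitochondrial UMIs were 30.0%, 34.6% and 26.5% in livers R230, R232 and R235, and 0.219% to 6.06% in the others. Scrublet, run per library in scanpy 1.11.5 with an expected rate of 6%, marked 0% to 0.462% of cells, so the caller did not work here and doublets remain. Cells were clustered on 2000 variable genes, 30 principal components and 20 neighbours with leidenalg 0.10.2 at resolution 1, and clusters were named only from fixed marker lists. Clusters named monocyte and macrophage-like or B and plasma cell-like were left out, 0 to 118 cells per library compared and 185 in liver R227. Unnamed clusters with few CD3 UMIs stayed among the T cells. The remaining cells were summed per library over all T cells, over the CD8 transcript class and over the CD4 transcript class. Cells are not replicates, and each sum is 1 replicate of its organ.

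Sums were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM factors, filterByExpr and robust fitting, and Benjamini-Hochberg adjustment at 0.05. Log2 fold changes are lung minus liver, and the standard error is the fold divided by the square root of the F statistic. The difference between the classes was tested as a class-by-organ term with the library as a factor. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and with an estimated one. Shares of cells were compared by two-sided exact permutation tests after thinning each cell to 1000 UMIs, which left out 111 to 874 shallower cells per library: 191, 111, 471, 415 and 151 in livers R230, R232, R235, R276 and R312, and 126, 874, 412, 737 and 738 in lungs R230, R233, R235, R276 and R312. Intervals of shares are 95% exact binomial intervals and cover counting error only. Clonality is 1 minus the normalised entropy of clonotype frequencies, as the mean of 100 draws of 614 cells. A shared clonotype has identical alpha and beta CDR3 nucleotide sequences in both organs, and only clonotypes with at least 1 chain of each kind were counted. Permutation tests used Python 3.11.15 and scipy 1.17.1.

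The samples, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule named, among genes with a symbol that passed the threshold over all T cells with the same sign in all 4 animals with both organs, a mean of at least 4 log2 CPM and a UMI in at least 5% of T cells, the 10 with the largest fold in each direction outside the lists of other cell types. It also named the 4 members of each list with the smallest p, the 3 genes per direction with the smallest adjusted p in each class and in the difference between classes, and 14 T cell genes in any case. Of the list members, mainly those that passed the threshold with or without the block are printed, and 1 of these is not reported here. TCR and immunoglobulin segment genes were tested and are not named. The gene lists were: tissue residency, naive and recirculation, cytotoxicity, inhibitory receptors and exhaustion, activation and costimulation, secreted cytokines and chemokines, Th1, Th2, Th17, regulatory T cell, chemokine receptors and homing, cell cycle, type I interferon response, interferon gamma response, NF-kB targets, immediate early genes, heat shock, glycolysis, hypoxia, oxidative phosphorylation, cholesterol synthesis, fatty acid uptake and oxidation, TGF-beta response, amino acid and integrated stress response, p53 targets, and lists of 12 other cell types.

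Replicate numbers in the labels are animal names, so lung and liver of the same number come from the same animal and are paired. Over 6788 genes, the deviation of a liver from its organ mean correlated with that of its own lung at 0.47 for R230, 0.70 for R235, 0.21 for R276 and 0.01 for R312, with highest values against another lung of 0.21, -0.15, 0.05 and 0.21. The fit without the block is the main result and the fit with the animal as a block an alternative. Further alternatives fixed in advance were the 8 paired libraries without a block, R227 added, DESeq2 1.42.0, relative log expression factors, no filter on low counts, all barcodes, libraries thinned to the smallest total, genes of other cell types left out, other thinning depths, no rarefaction, and each library left out in turn. Batch 2 libraries alone, batch as a term, cells with a CD3 UMI alone, shares of all TCR cells, gene and list counts without livers R230, R232 and R235, and the block or batch 2 with an estimated correlation were chosen after seeing the data.

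The tests were tried on simulated counts of the genes and library sizes measured here, with 200 genes changed by known folds. At 1.5-fold, 2-fold and 4-fold, 4.48%, 27.7% and 72.3% were recovered over all T cells (12453 genes, 2 false calls), 3.03%, 35.4% and 81.3% in the CD8 class (11540 genes, 6 false calls), 3.08%, 40.0% and 98.4% in the CD4 class (8905 genes, 7 false calls), and 25.4%, 58.5% and 86.4% for the difference between classes (10722 genes, 7 false calls). With the cell cycle list lowered in simulated data, camera called it and 1 other list of 34. Simulated counts were drawn independently for each gene and library, without pairing of organs. Recovery in the measured data may therefore differ, and camera was not tried on correlated genes. In the simulation over all T cells few genes changed by under 2-fold were found.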

Results

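T cells were profiled from the liver and the lungs of rhesus macaques after hematopoietic cell transplantation. In acute graft-versus-host disease, donor T cells attack the organs of the recipient, and the series title names differences between organs as its subject. Per the labels, conditioning was 1040 cGy of total body irradiation, the graft was a peripheral blood stem cell product, no immunosuppression was given, and tissue was taken at a preset endpoint on day 8 or at clinical endpoints. The protocol covers MHC-haploidentical and autologous transplants, and the labels do not say which animal received which. Each tissue was measured by droplet sequencing of messenger RNA from its 5' end, with a T cell receptor (TCR) library from the same cells. Expression libraries came from 6 livers and 5 lungs. Liver R227 is not part of the authors' filtered objects, per the labels, and was kept out of the main comparisons, which therefore set 5 livers against 5 lungs. Of these, 4 animals (R230, R235, R276 and R312) gave both organs, R232 gave liver and R233 gave lung. Each animal is a replicate within an organ. The libraries compared held 1501 T cells (lung R230) to 9623 T cells (lung R233), with 9452767 UMIs (lung R230) to 49548169 UMIs (liver R312) in their T cells and a median of 2188 UMIs (liver R235) to 5966 UMIs (liver R312) per T cell.

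The first comparison asked which genes differed between lung and liver over all T cells. Among the genes lower in lung, CDCA7, a chromatin factor of dividing cells, had a log2 fold change of -1.50 (SE 0.16, adjusted p = 0.00494), FEN1, the flap endonuclease of DNA replication, had -1.44 (SE 0.21, adjusted p = 0.0115), and BUB1, a kinase of the spindle checkpoint, had -1.44 (SE 0.22, adjusted p = 0.0115). FH, the fumarate hydratase of the citric acid cycle, was also lower in lung (-1.47, SE 0.23, adjusted p = 0.0122), as were ACTL6A, a subunit of BAF chromatin remodelling complexes (-1.43, SE 0.16, adjusted p = 0.00511), and OPN3, a member of the opsin family (-1.43, SE 0.23, adjusted p = 0.0125). Higher in lung were SMAD7, an inhibitor of TGF-beta signalling (1.61, SE 0.21, adjusted p = 0.00748), KLF3, a Krüppel-like transcription factor (1.71, SE 0.26, adjusted p = 0.0118), and S1PR5, a sphingosine-1-phosphate receptor (2.03, SE 0.28, adjusted p = 0.00748). In the deposited gene list their identifiers are ENSMMUG00000014228 (CDCA7), ENSMMUG00000006657 (FEN1), ENSMMUG00000017653 (BUB1), ENSMMUG00000005667 (FH), ENSMMUG00000009742 (ACTL6A), ENSMMUG00000005669 (OPN3), ENSMMUG00000056276 (SMAD7), ENSMMUG00000003363 (KLF3) and ENSMMUG00000008686 (S1PR5). These 9 genes differed in the same direction in 4 of 4 animals with both organs and passed the threshold in each of the 22 alternative settings run for them, leaving out any single library included. These settings do not include the fit without livers R230, R232 and R235 or the fit without cycling cells. There edgeR called 1 of 13530 and 0 of 11343 genes. Folds are lung minus liver on the log2 scale with n = 5 livers and 5 lungs, and adjusted p values are from the quasi-likelihood test of edgeR with Benjamini-Hochberg adjustment. Mean levels were 36.0 ± 3.75 CPM in liver and 12.7 ± 2.15 CPM in lung for CDCA7, and 30.3 ± 3.35 CPM in liver and 92.7 ± 30.8 CPM in lung for SMAD7 (SD, n = 5 each).

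Among batch 2 libraries alone, 3 livers and 5 lungs, the log2 fold change was -1.59 for CDCA7, -1.39 for FEN1, -1.38 for BUB1, -1.73 for FH, -1.39 for ACTL6A, -1.67 for OPN3, 1.63 for SMAD7, 1.78 for KLF3 and 1.98 for S1PR5. Batch 1 holds livers only (R227, R276 and R312), so it gives no value of its own. The labels do not state what defines a batch. The batch 2 livers are R230, R232 and R235. Of the livers compared, these had the highest shares of barcodes left out for mitochondrial UMIs. Values among batch 2 libraries, here and below, therefore do not separate the organs from liver quality by that measure.

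In total 601 of 12621 genes differed, 188 higher in lung and 413 higher in liver, and 2864 genes had an unadjusted p under 0.05. Among batch 2 libraries 591 of 12397 genes differed, 365 of them among the 601. With the animal as a block the count was 731, of which 410 were among the 601. The count depended on single libraries: it was 43 without lung R235, 120 without lung R230, 154 without lung R312, 190 without lung R276, 191 without liver R232, 371 without liver R235 and 383 without liver R230. The direction of the 601 genes held in these settings wherever they were tested. DESeq2 called 1291 genes. In livers R230, R232 and R235, 30.0%, 34.6% and 26.5% of barcodes had over 10% mitochondrial UMIs and were left out, against 0.219% in liver R276, 0.313% in liver R312 and 0.399% to 6.06% in the lungs. Without these 3 livers, which leaves 2 livers of batch 1 against 5 lungs of batch 2, edgeR called 1 of 13530 genes (2753 at an unadjusted p under 0.05, DESeq2 not run), and 601 of the 601 genes kept their direction. These refits reuse libraries by which the 601 genes were chosen, so a held direction, here and above, is not independent support. The share of cells with a CD3 UMI was 59.2% in liver R232 and 57.1% in liver R235 against 77.4% to 97.6% in the other libraries compared, and liver R312 stood apart on the first principal component (-53.5, with the others between -13.2 and 26.5).

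The other leading genes higher in liver were CAVIN3, a coat protein of caveolae (-2.99, SE 0.47, adjusted p = 0.0131), GPAT3, an enzyme of glycerolipid synthesis (-2.08, SE 0.39, adjusted p = 0.0192), PSAT1, an enzyme of serine synthesis (-1.76, SE 0.37, adjusted p = 0.0264), and CDC20, an activator of the anaphase-promoting complex (-1.51, SE 0.28, adjusted p = 0.0181). CAVIN3 was called in 21 of 22 alternatives (adjusted p = 0.0503 without lung R235). GPAT3 was called in 19 (not without lung R230, lung R235 or lung R312, adjusted p up to 0.0544), CDC20 in 20 (not without lung R230 or lung R235, up to 0.0539) and PSAT1 in 14 (not without lung R230, liver R232, lung R235, lung R276 or lung R312), with adjusted p = 0.0616 among batch 2 libraries and up to 0.0879 over all alternatives. The other leading genes higher in lung were SIPA1L2 (1.75, SE 0.41), ABLIM1, an actin-binding protein (1.37, SE 0.35), MPP7 (1.32, SE 0.30), TRIB2, a pseudokinase (1.23, SE 0.27), FLT3LG, the ligand of the receptor FLT3 (1.19, SE 0.30), AHNAK, a large scaffold protein (1.18, SE 0.26), NUCB2 (1.15, SE 0.24) and SKIL, a repressor of SMAD transcription factors (1.14, SE 0.27). Their adjusted p ran from 0.0258 (NUCB2) to 0.0446 (ABLIM1), and each was called in 10 to 15 of 22 alternatives. Leaving out lung R230, liver R235, lung R235 or lung R312 ended the call of each of these 8 genes. Leaving out liver R232 ended that of 7, lung R276 that of 6, lung R233 and liver R230 that of 3 each, liver R312 that of SIPA1L2 and FLT3LG, and liver R276 that of SIPA1L2, with adjusted p up to 0.130 (FLT3LG) over all alternatives and the same direction throughout. SIPA1L2 was not called among batch 2 libraries (adjusted p = 0.106). Batch as a term ended further calls, among them those of SIPA1L2 (adjusted p = 0.113), FLT3LG (adjusted p = 0.0953), NUCB2 (adjusted p = 0.0601), TRIB2 (adjusted p = 0.0576) and AHNAK (adjusted p = 0.0562). With the animal as a block the calls of ABLIM1 (adjusted p = 0.103), MPP7 (adjusted p = 0.0628) and SKIL (adjusted p = 0.0576) ended.

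**Figure D1:**
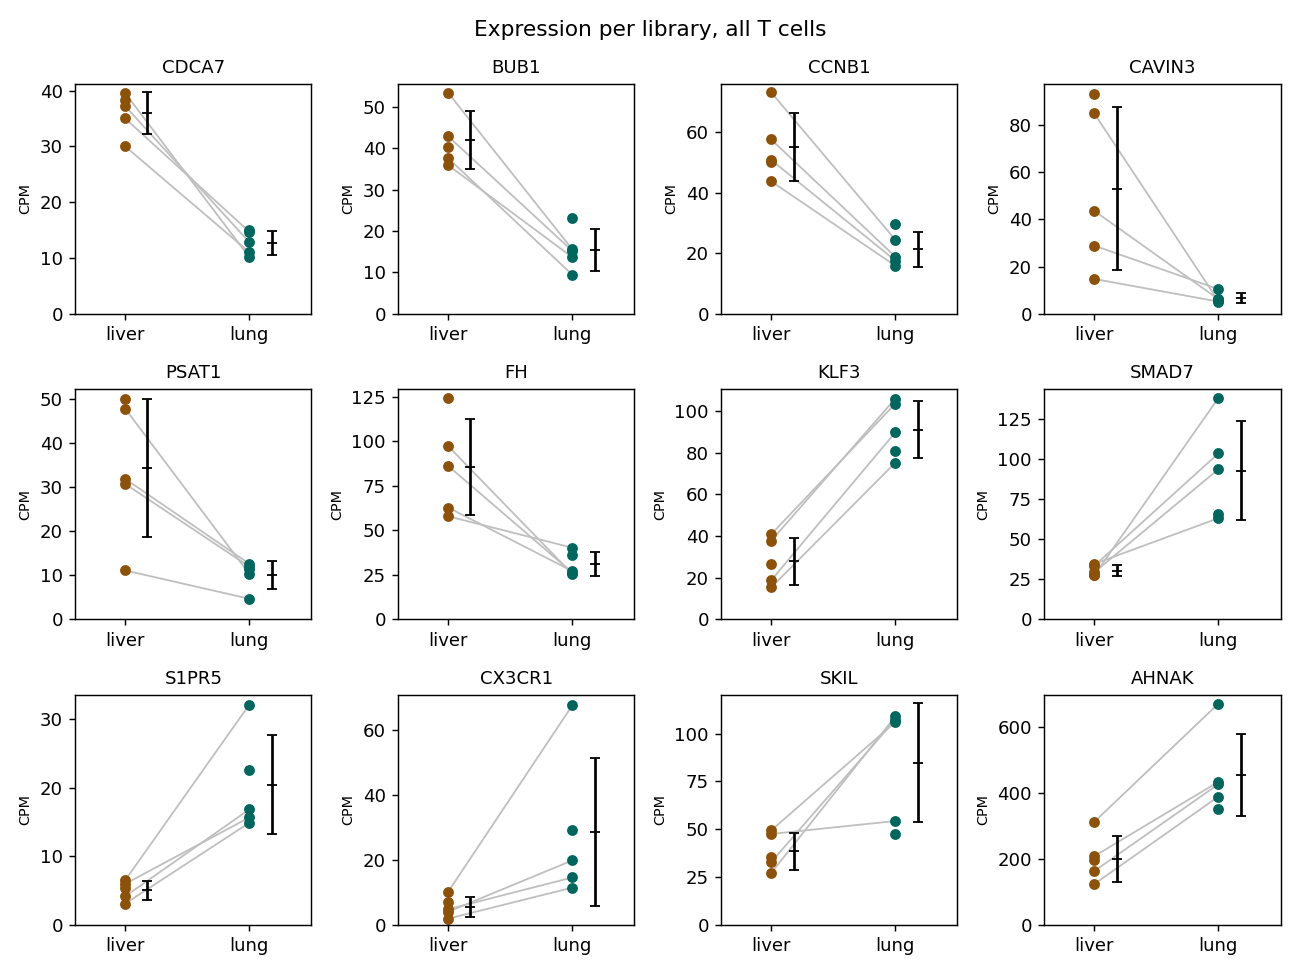
Expression in CPM of 12 genes in the T cells of each library, with brown points for 5 livers, teal points for 5 lungs, grey lines joining the organs of an animal, and black marks for the mean ± SD. CDCA7 lies at 36.0 ± 3.75 CPM in liver and 12.7 ± 2.15 CPM in lung, and SMAD7 at 30.3 ± 3.35 CPM in liver and 92.7 ± 30.8 CPM in lung.

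Of the 27 cell cycle genes tested, 14 were lower in lung and 0 higher, and 23 were lower when adjusted over the list alone. CCNB1 and CCNB2, the B-type cyclins of mitosis, had log2 fold changes of -1.37 (SE 0.20, adjusted p = 0.0115) and -1.32 (SE 0.25, adjusted p = 0.0191), AURKA, a mitotic kinase, had -1.52 (SE 0.26, adjusted p = 0.0147), and TYMS, the thymidylate synthase, had -1.22 (SE 0.24, adjusted p = 0.0208). The call of AURKA ended without lung R235 (adjusted p = 0.0539), as did that of TYMS (adjusted p = 0.0616), and that of CCNB2 without lung R230, without lung R235 and with batch as a term (adjusted p up to 0.0540). MKI67, the proliferation marker, had -0.59 (SE 0.27, adjusted p = 0.211) and was not called. The median over the list was -0.78, and camera, which compares a list with all other genes at a preset correlation of 0.01, gave adjusted p = 3.07e-18. The call was lost with adjusted p = 0.314 with an estimated correlation. Among batch 2 libraries the preset test gave adjusted p = 8.57e-11.

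Camera at the preset correlation called 7 of 34 lists, cell cycle included, and 0 of them held with an estimated correlation. In naive and recirculation genes, higher in lung as a list (median 0.64, adjusted p = 7.46e-05), S1PR5 and KLF3 were higher among 15 tested, the same 2 adjusted over the list alone, while TCF7 (0.73, SE 0.44) and CCR7 (0.74, SE 0.54), a transcription factor and a homing receptor of naive and memory cells, did not pass. In TGF-beta response genes (median 0.75, adjusted p = 9.36e-05), SMAD7 and SKIL were higher among 14 tested and 5 adjusted over the list alone. Both SMAD7 and SKIL are known as negative regulators of the pathway. For these 2 lists adjusted p = 0.314 with an estimated correlation. Type I interferon response genes (median 0.51, adjusted p = 0.000287) had 1 of 24 higher in lung and 2 adjusted over the list alone, among them EPSTI1 (0.82, SE 0.21, adjusted p = 0.0453), which was not called among batch 2 libraries (adjusted p = 0.124), was called in 7 of 22 alternatives, and lost its call when any of the 10 libraries was left out (adjusted p up to 0.108, and 0.141 over all alternatives). Immediate early genes (median 0.60, adjusted p = 0.000545) had 0 of 21 called by edgeR or DESeq2, also adjusted over the list alone (2 at an unadjusted p under 0.05), and NF-kB targets (median 0.49, adjusted p = 0.00107) had 1 of 15, also adjusted over the list alone. That gene was NFKB2, a subunit of the factor itself (1.00, SE 0.25, adjusted p = 0.0435). It was called in 7 of 22 alternatives (adjusted p up to 0.127), not when a library other than lung R276 was left out, and not with the block (adjusted p = 0.0952) or among batch 2 libraries (adjusted p = 0.0936). Oxidative phosphorylation genes were lower in lung as a list (median -0.22, adjusted p = 0.0302), with 1 of 20 lower and 2 adjusted over the list alone. The gene was SDHA, a subunit of succinate dehydrogenase (-0.54, SE 0.13, adjusted p = 0.0342). It was called in 10 of 22 alternatives (adjusted p up to 0.0946), not without liver R230, lung R230, liver R232, liver R235, lung R235, lung R276 or lung R312, and not with the block (adjusted p = 0.0655) or among batch 2 libraries (adjusted p = 0.0553). For these 4 lists adjusted p = 0.686 with an estimated correlation. Among batch 2 libraries the preset test gave adjusted p = 0.000222 for naive and recirculation, 0.000263 for TGF-beta response, 2.51e-08 for type I interferon, 0.0664 for immediate early genes, 0.108 for NF-kB targets and 0.322 for oxidative phosphorylation, and 0 lists held there with an estimated correlation. Without liver R312 it gave 0.0541 for immediate early genes and 0.0815 for oxidative phosphorylation.

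**Figure D2:**
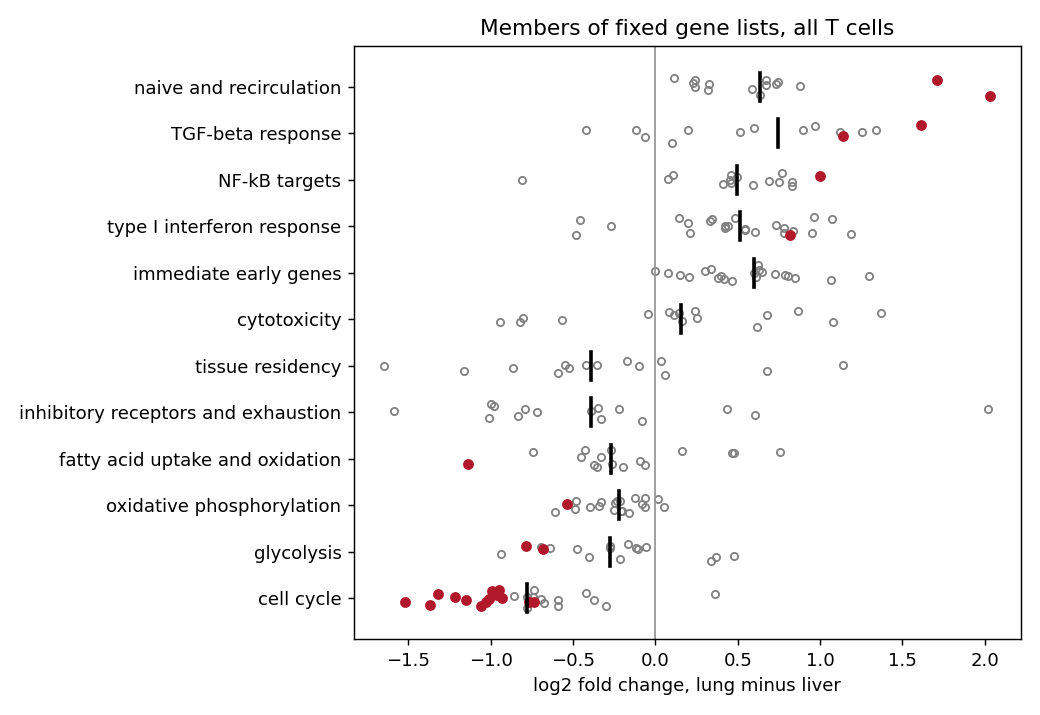
Log2 fold change, lung minus liver, of each tested member of 12 gene lists over all T cells, with filled red points for members past the threshold and a bar at the median of the list. The medians include -0.78 for cell cycle genes, 0.75 for TGF-beta response and 0.64 for naive and recirculation.

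Over the 10 libraries, lists of T cell function other than naive and recirculation were not called at the preset correlation without the block. Tissue residency genes had 0 of 14 past the threshold of edgeR, also adjusted over the list alone (5 at an unadjusted p under 0.05, median -0.39, adjusted p = 0.537). DESeq2 called 2 of them, CXCR6 (adjusted p = 0.0330) and CRTAM (1.15, adjusted p = 0.0463). PRDM1 (-0.59, SE 0.20) was called among batch 2 libraries (adjusted p = 0.0284) and without liver R312 (adjusted p = 0.0464), with adjusted p up to 0.230 over its alternatives. CXCR6, a chemokine receptor of resident T cells, had -1.65 (SE 0.60, adjusted p = 0.133) over all libraries and -0.44 among batch 2 libraries, and ITGAE, the alpha chain of the integrin CD103, had -0.42 (SE 0.34) over all libraries and 0.17 among batch 2 libraries. CD69 had 0.68 (SE 0.39, adjusted p = 0.333). Cytotoxicity genes had 0 of 16 by edgeR, also adjusted over the list alone (5 at an unadjusted p under 0.05, median 0.15, adjusted p = 0.537). DESeq2 called 1, FASLG, the gene of Fas ligand (-0.79, adjusted p = 0.0297), also called by edgeR with R227 added (adjusted p = 0.0384, up to 0.204 over its alternatives). GZMB, the granzyme B gene, had 0.08 (SE 0.40). PRF1, the gene of perforin, had -0.82 (SE 0.29) and GZMM had 1.08 (SE 0.41), and each was called with the animal as a block (adjusted p = 0.0435 and 0.0340). PRF1 was also called without lung R233 (adjusted p = 0.0360). Over their alternatives adjusted p reached 0.256 for PRF1 and 0.339 for GZMM. Inhibitory receptors and exhaustion genes had 0 of 15 by edgeR, also adjusted over the list alone (6 at an unadjusted p under 0.05, median -0.39, adjusted p = 0.0743). DESeq2 called 2, ENTPD1 (adjusted p = 0.00606) and TIGIT (adjusted p = 0.0370). That list was called with the block (adjusted p = 0.0115) and among batch 2 libraries (adjusted p = 0.0249), and both calls were lost with an estimated correlation (adjusted p = 0.777 and 0.397). Its members ENTPD1 (-1.59, SE 0.46), TIGIT (-1.0, SE 0.33) and LAG3 (-0.72, SE 0.26), which encode an ectonucleotidase and a pair of inhibitory receptors, were called with the block (adjusted p = 0.0403, 0.02 and 0.0299). ENTPD1 was also called without liver R230 (adjusted p = 0.0479) and LAG3 without lung R233 (adjusted p = 0.0428). Over their alternatives adjusted p reached 0.289 (TIGIT). PDCD1, the gene of PD-1, had -0.33 (SE 0.22). Activation and costimulation genes had 0 of 14 by edgeR, also adjusted over the list alone (2 at an unadjusted p under 0.05, 2 called by DESeq2, median 0.28, adjusted p = 0.321).

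Secreted cytokines and chemokines had 1 of 19 lower in lung, also adjusted over the list alone (median -0.28, adjusted p = 0.882, and 0.0130 among batch 2 libraries, where adjusted p = 0.562 with an estimated correlation). The member was CSF2, the gene of GM-CSF (-3.78, SE 0.87, adjusted p = 0.0342), lower in lung in 3 of 4 animals, called in 11 of 22 alternatives and not with the block (-2.86, adjusted p = 0.305). Its call ended without any of liver R230, liver R232, liver R235 and the 5 lungs, each left out singly (adjusted p up to 0.305 over all alternatives). IFNG, the interferon gamma gene, had -0.32 (SE 0.46). Chemokine receptors and homing genes had 1 of 23 higher in lung and 1 lower, also adjusted over the list alone (median 0.01, mean -0.08, test upward with adjusted p = 0.819). CCR9, a gut-homing receptor, had -2.72 (SE 0.53, adjusted p = 0.0208), -3.00 among batch 2 libraries, and was not called without lung R230, lung R235, lung R276 or lung R312 (adjusted p up to 0.0580). CX3CR1, the fractalkine receptor, had 2.36 (SE 0.54, adjusted p = 0.0324), was not called among batch 2 libraries (adjusted p = 0.0578), was called in 9 of 22 alternatives (adjusted p up to 0.101) and lost its call when any library but liver R276 was left out. By edgeR, Th1 genes had 0 of 10 (1 lower in lung adjusted over the list alone, median -0.23, adjusted p = 0.546), Th2 genes 0 of 9 (0 adjusted over the list alone, median -0.55, adjusted p = 0.960) and Th17 genes 0 of 13 (0 adjusted over the list alone, adjusted p = 0.599, with a median of -0.17 and a test direction upward). At an unadjusted p under 0.05 there were 4 Th1 genes, 1 Th2 gene and 1 Th17 gene, and DESeq2 called 1, 1 and 0. CXCR3 (-0.71, SE 0.31), a chemokine receptor of the Th1 list, was called with the block (adjusted p = 0.0227) and in no other alternative (adjusted p up to 0.468). Regulatory T cell genes had 0 of 13 by edgeR (5 at an unadjusted p under 0.05, 3 called by DESeq2, 1 higher and 2 lower adjusted over the list alone, median -0.58, adjusted p = 0.599), and FOXP3, their lineage factor, had -0.75 (SE 0.38, adjusted p = 0.266).

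Metabolic and stress lists gave single genes. Glycolysis had 2 of 17 lower in lung and 4 adjusted over the list alone (median -0.28, adjusted p = 0.0649, and 0.0130 among batch 2 libraries, where adjusted p = 0.461 with an estimated correlation). ENO1, the enolase (-0.68, SE 0.16, adjusted p = 0.0347), and PGAM1, the phosphoglycerate mutase (-0.79, SE 0.19, adjusted p = 0.0357), were not called among batch 2 libraries (adjusted p = 0.0780 and 0.0566) and were called in 9 of 22 alternatives each (adjusted p up to 0.105). Both lost their call when a library was left out, except liver R312 for both and liver R235 for ENO1. Hypoxia had 1 of 13 higher and 2 lower, with 3 higher and 2 lower adjusted over the list alone (median 0.18, adjusted p = 0.357). P4HA2, a prolyl hydroxylase (-2.63, SE 0.49, adjusted p = 0.0169, at 0.741 ± 0.225 CPM in lung), and CA9, a carbonic anhydrase (-1.38, SE 0.32, adjusted p = 0.0317), were lower in lung, and BNIP3L, a mitophagy receptor (0.60, SE 0.12, adjusted p = 0.0222), was higher, though not with the block (adjusted p = 0.0512). P4HA2 was called in 19 of 22 alternatives, not without lung R230 or lung R235 (adjusted p up to 0.0550 over all alternatives). CA9 was called in 15 and BNIP3L in 14, and leaving out lung R230, liver R232, lung R235, lung R276 or lung R312 ended the call of both, and liver R230 or liver R235 that of CA9 (adjusted p up to 0.0879). Fatty acid uptake and oxidation had 1 of 16 lower and 3 adjusted over the list alone (median -0.27, adjusted p = 0.258), with CPT2, a carnitine palmitoyltransferase (-1.14, SE 0.25, adjusted p = 0.0290), not called with the block (adjusted p = 0.0569), called in 13 of 22 alternatives (adjusted p up to 0.0844), and not called without liver R230, lung R230, liver R232, lung R235, lung R276 or lung R312. Amino acid and integrated stress response genes had 1 of 16 lower, also adjusted over the list alone (median -0.04, adjusted p = 0.657), and this was PSAT1. No member was called by edgeR in cholesterol synthesis (0 of 19, 0 adjusted over the list alone, median -0.21, adjusted p = 0.387), heat shock (0 of 13, 0 adjusted over the list alone, median 0.02, adjusted p = 0.825), interferon gamma response (0 of 17, 0 adjusted over the list alone, median 0.16, adjusted p = 0.250) or p53 targets (0 of 13, 1 higher adjusted over the list alone, median 0.26, adjusted p = 0.0743). DESeq2 called 2, 0, 2 and 1 members of these 4 lists, and 3, 1, 5 and 2 had an unadjusted p under 0.05 in edgeR. The p53 list was called with the block (adjusted p = 0.0372), and not with an estimated correlation (adjusted p = 0.797). Of other members named by the rule, the block called SATB1 (0.92, adjusted p = 0.0497), IER5 (0.83, adjusted p = 0.0428), LDLRAD4 (1.41, adjusted p = 0.0306), TGFBR3 (1.20, adjusted p = 0.0236), CIITA (1.5, adjusted p = 0.0448), ACADM (-0.81, adjusted p = 0.0486), PHGDH (-1.08, adjusted p = 0.0349) and CD8B (-0.73, adjusted p = 0.0486), and edgeR called none of these 8 over all T cells of the 10 libraries. DESeq2 called LDLRAD4 (adjusted p = 0.00768), TGFBR3 (adjusted p = 0.0164) and ACADM (adjusted p = 0.0243), and edgeR called TGFBR3 and ACADM in cells with a CD3 UMI (adjusted p = 0.0386 and 0.0488) and these 3 genes with R227 added. LDLRAD4 was also called without lung R233 (adjusted p = 0.0353) and CIITA without liver R276 (adjusted p = 0.0475). Over their alternatives adjusted p of these 8 genes reached 0.593 (CD8B).

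Markers of other cell types were few among the genes tested. Hepatocyte genes had 1 of 3 tested members higher in lung, also adjusted over the list alone (median -0.19, mean 0.26, test upward with adjusted p = 0.418). This was SERPINA1, the gene of alpha-1 antitrypsin (1.84, SE 0.33, adjusted p = 0.0167, 1.80 among batch 2 libraries), which also leads several clusters of cells with CD3 UMIs here. Neutrophil genes had 1 of 1, also adjusted over the list alone. CXCR2, a chemokine receptor, had 2.24 (SE 0.53, adjusted p = 0.0340) at 1.73 ± 0.740 CPM in lung, and was not called among batch 2 libraries (adjusted p = 0.0899) or when a library other than liver R232 or liver R312 was left out (adjusted p up to 0.0783, and 0.113 over all alternatives). No member was called by edgeR among bile duct (0 of 2), lung epithelium (0 of 3, adjusted p = 0.892), endothelium (0 of 7, adjusted p = 0.836), fibroblast (0 of 7, adjusted p = 0.181) or dendritic and mast cell genes (0 of 3, adjusted p = 0.599). The same held for monocyte and macrophage (0 of 6, adjusted p = 0.656, with a median of 0.05, a mean of 0.18 and a test direction downward), B and plasma cell (0 of 8, adjusted p = 0.400), NK cell (0 of 8, adjusted p = 0.321, and 0.0353 among batch 2 libraries, where adjusted p = 0.397 with an estimated correlation), erythroid (0 of 3, adjusted p = 0.599) and platelet genes (0 of 1). DESeq2 called 1 member each of the monocyte and macrophage, B and plasma cell, and NK cell lists and 0 of the other lists in this count. At an unadjusted p under 0.05 edgeR had 2 fibroblast, 2 monocyte and macrophage, 4 B and plasma cell, 1 NK cell and 1 platelet gene. Adjusted over the list alone, 1 monocyte gene and 1 B and plasma cell gene were lower in lung, 1 platelet gene was higher, and 0 passed in the other lists. Lists with under 3 tested members were not tested as lists. HOPX, on the lung epithelium list, is also on the cytotoxicity list.

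CD3E (0.01, SE 0.19), CD4 (0.19, SE 0.32), CD8A (-0.46, SE 0.24) and CD8B (-0.41, SE 0.26), which encode the T cell receptor complex and its coreceptors, were not called over all T cells without the block.

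The next comparisons asked whether the organ difference is found within CD8 and CD4 T cells. Cells with a CD8A or CD8B UMI and no CD4 UMI formed the CD8 transcript class, and those with the reverse formed the CD4 transcript class. These are transcript gates, not cell types: 18.5% to 54.9% of the T cells of a library had neither and 3.06% to 11% had both. In the CD8 class SMAD7 (1.67, SE 0.25, adjusted p = 0.0181), TFDP2, a partner of E2F transcription factors (1.09, SE 0.17, adjusted p = 0.0181), and ARRDC2, an arrestin-domain protein (0.91, SE 0.14, adjusted p = 0.0181), were higher in lung. CDCA7 (-1.44, SE 0.15, adjusted p = 0.00575), ACTL6A (-1.29, SE 0.17, adjusted p = 0.0181) and FEN1 (-1.27, SE 0.19, adjusted p = 0.0181) were lower. CDCA7 was called in 21 of 22 alternatives, SMAD7 in 20, TFDP2, ACTL6A and FEN1 in 19 each and ARRDC2 in 18, and all 6 with the block and among batch 2 libraries. Over the 8 paired libraries without a block none of them was called (adjusted p up to 0.0828). Leaving out lung R235 ended the call of all but CDCA7 (adjusted p = 0.0570). Leaving out lung R276 ended that of TFDP2, ARRDC2, ACTL6A and FEN1 (adjusted p up to 0.0553), and liver R232 that of ARRDC2 (adjusted p = 0.0543). In total 301 of 11685 genes differed, 113 higher in lung and 188 lower, with 390 among batch 2 libraries. The count was 1 without lung R235, 3 without lung R276, 23 without liver R232, 29 without lung R230, 55 without liver R235, 60 without lung R312, 133 without lung R233 and 199 without liver R230. It was 0 with edgeR over the 8 libraries of the 4 animals without a block (1974 genes at an unadjusted p under 0.05, 293 called with the block), while DESeq2 called 1009 over the 10 libraries. Without livers R230, R232 and R235 edgeR called 0 of 12380 genes (2084 at an unadjusted p under 0.05, DESeq2 not run), and 301 of the 301 genes kept their direction. The refit reuses libraries by which the 301 genes were chosen, so this direction is not independent support.

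In the CD4 class, edgeR called 0 of 9092 genes, 1316 had an unadjusted p under 0.05, and DESeq2 called 119. The folds of the genes above were -1.61 for CDCA7 (adjusted p = 0.123), 1.39 for SMAD7 (adjusted p = 0.0878) and -1.35 for ACTL6A (adjusted p = 0.0844). DESeq2 called these 3 genes (adjusted p = 0.00738, 0.000795 and 0.000145), and so did edgeR without liver R312 (adjusted p = 0.0136, 0.0489 and 0.0312). Without the filter on low counts edgeR called SMAD7 and ACTL6A (adjusted p = 0.0431 and 0.0495), and with R227 added ACTL6A (adjusted p = 0.0406). Over their alternatives adjusted p reached 0.304 (CDCA7). Without liver R312 the count was 36, among batch 2 libraries 0, and with R227 added 2. In simulated data of the same size, 98.4% of genes changed 4-fold and 40.0% of genes changed 2-fold were recovered in this class. The simulated genes and libraries were independent of each other, so these shares may not hold for the measured data. They do not show that large changes are absent in the CD4 class.

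Whether the organ difference differed between the classes was tested directly. CAVIN3 was lower in lung in the CD8 class (-3.19) and near equal in the CD4 class (-0.12), a difference of -3.08 (SE 0.34, adjusted p = 0.00182). TIGIT (-0.94, SE 0.14, adjusted p = 0.00599) and CASK, a membrane scaffold kinase (-1.0, SE 0.14, adjusted p = 0.00599), also had a lower fold in the CD8 class. A higher one was found for RNASE6, a ribonuclease (1.04, SE 0.17, adjusted p = 0.0131), LGMN, the lysosomal protease legumain (2.95, SE 0.49, adjusted p = 0.0131), and GBP3, a guanylate-binding protein (0.92, SE 0.16, adjusted p = 0.0224). LGMN was low: over all T cells it was at 10.0 CPM in liver R312 and at 0.275 to 2.96 CPM in the other libraries compared. Of 10838 genes, 54 differed, 12 with a higher and 42 with a lower fold in the CD8 class, and 46 differed among batch 2 libraries, where RNASE6, LGMN and GBP3 were not called. With animal-by-class terms in place of library terms, the block fitted for the 4 animals with both organs called 0 by edgeR (196 at an unadjusted p under 0.05), and no gene named here held (adjusted p = 1). Without a library term, that fit does not pair the class sums of a library as the main test does, so the counts are not like for like. GBP3 was also not called without liver R235, lung R235, liver R312 or lung R312 (adjusted p up to 0.0741 with these left out), nor LGMN without liver R312 (adjusted p = 0.101) or with all barcodes (adjusted p = 0.1). No other tool was run for this test. The count was 12 without lung R312, 18 without lung R235, 34 without liver R312, 35 without lung R233 and 82 without liver R230. It was 58 without livers R230, R232 and R235, with 25 of them among the 54.

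Shares of cells were compared after thinning each cell to 1000 UMIs. CD8 transcript cells were 92.6% ± 2.49 of the cells in either class in liver and 86.3% ± 6.91 in lung (SD, n = 5 each, exact permutation p = 0.127), lower in lung in 4 of 4 animals. The difference was -6.21 percentage points, -4.53 among batch 2 libraries (exact permutation p = 0.357) and -8.62 without lung R233 (exact permutation p = 0.0159). It was smaller without lung R312 (-4.71, exact permutation p = 0.230). Over the paired animals it was -8.89 (exact sign-flip p = 0.125, the smallest possible). Cells with a UMI of MKI67 or TOP2A, the gate for cycling used here, were 25.8% ± 8.95 in liver and 17.5% ± 4.53 in lung (SD, n = 5 each, exact permutation p = 0.119), lower in lung in 4 of 4 animals. The difference was -8.37 points, -10.5 among batch 2 libraries (exact permutation p = 0.107) and -11.1 without liver R230 (exact permutation p = 0.0397). It was smaller without liver R235 (-5.88, exact permutation p = 0.254) and without liver R232 (-6.53, exact permutation p = 0.238). Over the paired animals it was -7.29 (exact sign-flip p = 0.125, the smallest possible). At this depth the gate took 70.7% ± 13.5 in liver and 72.2% ± 6.69 in lung of the cells in clusters named cycling from cell cycle markers, and 21.5% ± 10.6 and 13.7% ± 3.84 of those in the other clusters (SD, n = 5 each). It took 1.95% of 871 cells in the naive or central memory-like cluster of liver R312. The other libraries compared held 0 to 20 such cells at this depth, too few for a background share. FOXP3-positive cells were 4.50% ± 2.20 of CD4 transcript cells in liver and 1.31% ± 0.637 in lung (SD, n = 5 each, exact permutation p = 0.00794, the smallest possible). Adjusted over these 3 shares the exact p was 0.0238, and the share was lower in lung in 4 of 4 animals. It rests on 1 to 10 cells per library with overlapping 95% exact binomial intervals, such as 2.14% to 18.5% in liver R235 and 0.0193% to 4.18% in lung R235, which cover counting error only. The difference was -3.24 among batch 2 libraries (exact permutation p = 0.0179, the smallest possible) and -3.69 over the paired animals (exact sign-flip p = 0.125, the smallest possible). At 500 UMIs the difference was -1.71 (exact permutation p = 0.127), lower in lung in 3 of 4 animals. With all barcodes it was -2.66 (exact permutation p = 0.0159), also lower in 3 of 4 animals. In cells with a CD3 UMI it was -3.00 (exact permutation p = 0.0317), again in 3 of 4 animals. Each cell was thinned in a single random draw, and the spread over draws was not measured. In CD8 transcript cells, which mostly lack FOXP3, the share was 0.171% to 2.12% in livers and 0.293% to 1.08% in lungs at the same 1000 UMIs per cell. In the lungs the CD4 transcript cells had 0.551% to 2.08%, with 95% intervals that overlap those of the CD8 transcript cells in each lung. Without thinning the liver and lung means were 88.2% and 80.6% for CD8 transcript cells, 45.7% and 35.1% for cells past the cycling gate, and 7.72% and 3.18% for FOXP3-positive cells. Tests were two-sided.

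**Figure D3:**
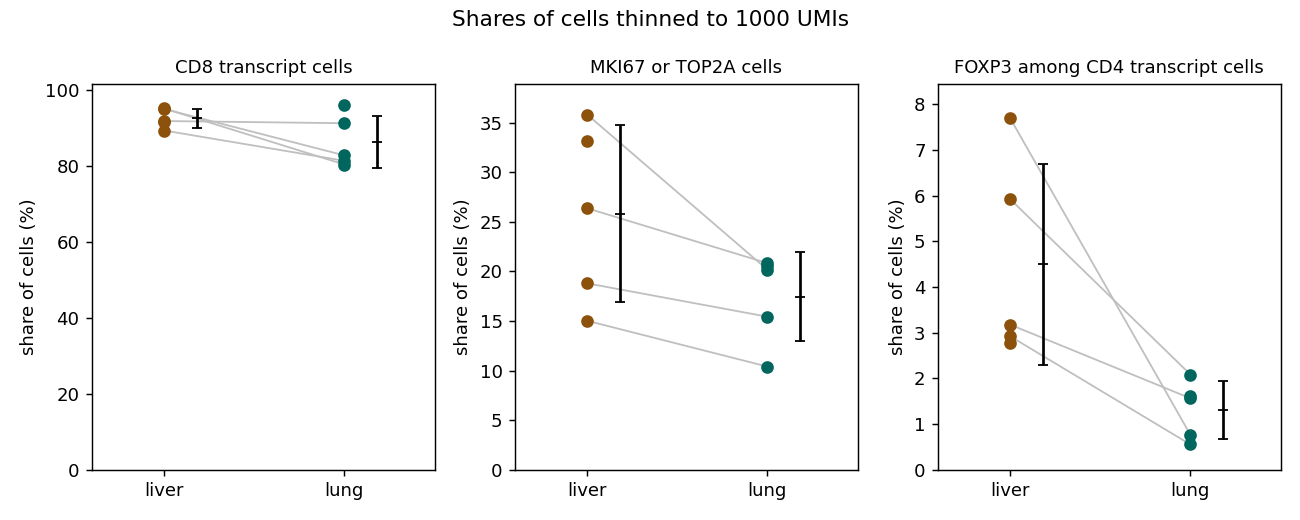
Percentage of CD8 transcript cells, cells with an MKI67 or TOP2A UMI and FOXP3-positive CD4 transcript cells in each library after thinning to 1000 UMIs per cell, with brown points for 5 livers, teal points for 5 lungs, grey lines joining the organs of an animal, and black marks for the mean ± SD. Means in liver and lung are 92.6% and 86.3%, 25.8% and 17.5%, and 4.50% and 1.31%.

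The TCR tables asked how far T cell clones were expanded and shared between the organs. Clonality, which is 0 when all clonotypes are equally frequent, was 0.0317 ± 0.0158 in liver (SD, n = 5) and 0.0610 ± 0.0458 in lung (SD, n = 3) after rarefaction to 614 cells, a difference of 0.0293 (exact permutation p = 0.179). The lung value was higher in 3 of 3 animals. Lung R276, where the largest clonotype held 466 of 3363 cells, set most of the difference between the organ means: without it the other lungs differed from the 5 livers by 0.00283 (exact permutation p = 0.857). Within animals, lung and liver were at 0.0344 and 0.0206 in R235 and at 0.0346 and 0.0213 in R312. Over the 3 paired animals the difference was 0.0401 (exact sign-flip p = 0.25, the smallest possible). Among batch 2 libraries, with livers R230, R232 and R235 against the 3 lungs, the difference was 0.0221 (exact permutation p = 0.7, with 0.1 the smallest possible), and batch 1 holds no lung. Without rarefaction the difference was 0.0524 (exact permutation p = 0.0357).

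Clonotypes of an animal's liver recurred in its lung. Only cells of clonotypes with at least 1 alpha and 1 beta chain were counted, which were 416 of 614 cells in liver R235, 998 of 1950 in liver R276 and 2135 of 3802 in liver R312. In the lungs they were 1031 of 1552, 2389 of 3363 and 2542 of 4453 in the same order. In the same animal 13.8% ± 3.44 of these liver cells and 20.4% ± 12.9 of these lung cells belonged to a clonotype found in both organs (SD, n = 3), a mean of 17.1%, against 0% between organs of different animals. Over all TCR cells the shares were 7.92% ± 1.38 of liver cells and 13.7% ± 9.88 of lung cells (SD, n = 3), a mean of 10.8%. A count of 0 allows up to 0.721% of the 416 cells of liver R235, the smallest number. R235 had 15 shared clonotypes, R276 had 25 and R312 had 54. The exact permutation p was 0.167, the smallest that 6 matchings of 3 animals allow, so this design cannot pass the threshold. Without R276 the mean was 12.4%. Among clonotypes of 2 or more cells it was 36.2%. Lungs and livers of R276 and R312 lie in different batches, and R235 alone has both organs in batch 2, where the shares of the cells counted were 12.3% in liver and 12.9% in lung, so no matching can be tested within a batch.

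**Figure D4:**
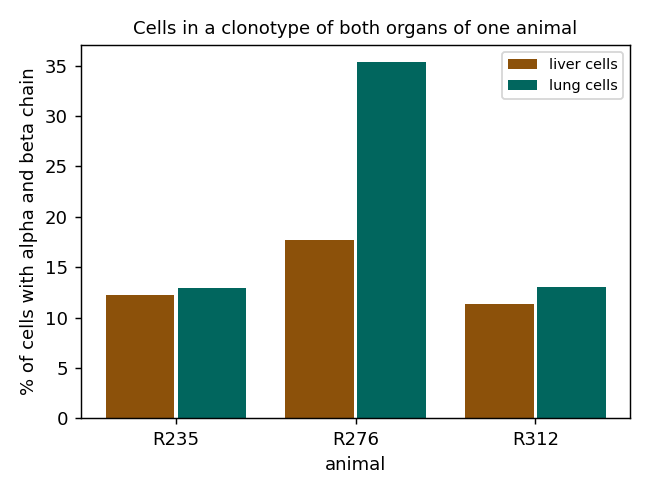
Percentage of liver and lung cells in a clonotype found in both organs of the same animal, as bars for R235, R276 and R312, among the cells of clonotypes with at least 1 alpha and 1 beta chain. The lung bars are 12.9%, 35.3% and 13.1% and the liver bars 12.3%, 17.7% and 11.4%, against 0% between organs of different animals.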

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

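The single-library values in this part come from a rule fixed before the data were examined, and only the batch 2 value of the difference between classes was chosen after the result was seen. The rule sets a library apart when its gap to the next one is large against the range of its organ, and it marks about 1 group in 20 by chance. Of 165 groups tested 7 were marked, against 8.25 by chance. Lung R235 had 28.2% of its T-cell UMIs in a pair of unnamed gene IDs, against a median of 8.18% in the other lungs. On the log2(CPM + 1) scale, CAVIN3 was at 3.51 in lung R312 (median of the other lungs 2.75), GPAT3 at 3.30 in lung R276 (4.05), PSAT1 at 2.49 in lung R235 (3.66) and CRTAM at 7.80 in lung R235 (7.05). ITGAE was at 8.16 in liver R312 (median of the other livers 6.45), and IFNG at 4.74 in liver R312 (7.75).

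The organ difference differed between the CD8 and CD4 transcript classes for 54 genes by the test of the difference itself, 46 among batch 2 libraries and 0 with the block, a fit without library terms. In liver R227, which the main comparisons leave out and which enters alternatives, 22% of T cells thinned to 1000 UMIs had a UMI of MKI67 or TOP2A (95% exact binomial interval 18.6% to 25.6%). It is given because that library holds such cells at all, and the 5 livers compared had 15% to 35.8%.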

How the results depend on the processing

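Batch 2 libraries, batch as a term, cells with a CD3 UMI, shares of all TCR cells, counts without livers R230, R232 and R235, and an estimated correlation with the block or batch 2 were chosen after seeing the data; the other alternatives were not. Over all T cells 601 genes differed, and 175 did over the 8 paired libraries without a block, 1291 with DESeq2, 340 with batch as a term, 1 without livers R230, R232 and R235, and 43 to 706 with a library left out, against 450 to 842 in the other alternatives. In the CD8 class 301 differed, and 0 did over the 8 paired libraries without a block or without these 3 livers, 526 with R227 added, 1009 with DESeq2, 185 with batch as a term, 492 in cells with a CD3 UMI, and 1 to 376 with a library left out, against 201 to 390 otherwise. In the CD4 class 0 differed, and 2 did with R227 added, 119 with DESeq2, 5 without the filter on low counts, 0 to 36 with a library left out, and 0 otherwise. Between the classes 54 differed, and 126 did without that filter, 0 with the block, which has no library terms, 12 to 82 with a library left out, and 44 to 70 otherwise. Lists numbered 7 and fell to 0 with an estimated correlation, alone, with the block or in batch 2, against 6 to 10 otherwise, 6 to 8 with a library left out. Fewer libraries enter the paired and left-out fits, and without the 3 livers organ and batch coincide; for the other moved counts the cause was not tested.

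The CD8 share differed by -8.62 to -4.71 points with a library left out, cells past the cycling gate by -11.1 to -5.88 points and FOXP3-positive cells by -3.61 to -2.39 points. FOXP3-positive cells differed by -1.71 points at 500 UMIs (exact permutation p = 0.127) and by -3.69 points with the block (exact sign-flip p = 0.125, the smallest possible). Clonality differed by 0.0524 without rarefaction (exact permutation p = 0.0357) and by 0.00283 to 0.0426 with a library left out. Sharing was 10.8% of all TCR cells, and 12.4% to 19.6% with an animal left out, where no p under 0.5 is possible. The cause of these changes was not tested.

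Of 1934 values of 90 gene results under alternatives, 1594 kept direction and side of the threshold, 277 lost and 46 gained a call, and 17 changed sign, none of them called. CD3E was at -0.13 with the block, -0.15 over the 8 paired libraries, -0.030 with R227 and -0.081 to 0.080 with a library left out, below 0 without liver R232, lung R233, liver R235 or lung R312. CD4 was at -0.026 in batch 2 and -0.027 with batch as a term. ITGAE was at 0.17 in batch 2, 0.17 with batch as a term and -0.55 to 0.14 with a library left out, above 0 without liver R312. GZMB was at -0.40 with the block, -0.45 over the 8 paired libraries, -0.027 with R227 and -0.42 to 0.28 with a library left out, below 0 without liver R230 or lung R233. The cause was not tested. Among the gene results given here and in the report, the block changed no call beyond those stated with it. The FOXP3 share rests on 1 to 10 cells per library.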

Other observations

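The tests of sequencing batch and of cell depth, the share of the cell cycle fold left without cycling cells, the list tests within the transcript classes and the batch 2 values were chosen after the result was seen; the tests of cycling cells, of cell number and of other splits were not.

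The gene lists were also tested within the transcript classes with camera at the preset correlation. In the CD4 class, where no single gene was called by edgeR (1316 at an unadjusted p under 0.05, 119 called by DESeq2), cell cycle genes were lower in lung as a list (adjusted p = 8.75e-13), and TGF-beta response and NF-kB target genes were higher (adjusted p = 0.000241 for both). With an estimated correlation these calls were lost (adjusted p = 0.597 for cell cycle and TGF-beta response and 0.639 for NF-kB targets). In the CD8 class the inhibitory receptors and exhaustion list was lower in lung (adjusted p = 0.01, and 0.566 with an estimated correlation). Its member BTLA, an inhibitory receptor, was at -1.57 (SE 0.27, adjusted p = 0.0238). BTLA also differed between the classes (-1.14, adjusted p = 0.0188) and was named here because it passed both tests, after its values were seen. The difference for BTLA was not called without lung R235 (adjusted p = 0.0586), without lung R312 (adjusted p = 0.0802) or with the block (-1.10, adjusted p = 1), and its adjusted p over the alternatives ran from 0.000447 to 1. Within the CD8 class BTLA was called in 16 of 22 alternatives, the block among them (adjusted p = 0.0183). It was not called over the 8 paired libraries without a block (adjusted p = 0.0980) or without lung R230, liver R232, liver R235, lung R235 or lung R276 (adjusted p up to 0.0612). Over all T cells BTLA was called in 0 of 22 alternatives.

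Other splits of the 10 libraries into 5 and 5 were refitted for 100 of the 126 possible. Over all T cells the real split gave 601 genes and the highest other 4, in the CD8 class 301 against 4, and for the difference between classes 54 against 7. In each, 1 split of 100 was as large, the real one itself, a share under the 0.05 set before the test. Most of these splits put both organs of some animal on the same side, unlike the real one, so they do not exclude chance. In the CD4 class 100 of 100 splits gave at least the real count of 0 (highest other 4). For lists 63 of 100 splits gave at least the real 7 (highest other 16), so chance is not excluded for the list calls. Among the 14 splits that part the animals with both organs as the real one does, the highest others were 2, 1, 0, 1 and 16 in the same order of all T cells, CD8 class, CD4 class, difference and lists. These 14 are too few for a share under 0.05, so the splits exclude chance for none of these counts. The count for the difference between classes was 0 with the animal as a block, a fit without library terms.

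Of 27 cell cycle genes 14 were lower in lung, MKI67 not among them, with a list call that was lost with an estimated correlation (adjusted p = 0.314), and batch and cell depth were weighed as technical sources. Among batch 2 libraries alone the median log2 fold change of the list was -0.74 (SD 0.38 over members). This lay further than 1 SD below 0, which argues against batch as the whole source. The livers of that batch are R230, R232 and R235, so the value does not separate the organs from liver quality. In R230 and R235, whose lung cells had more UMIs than their liver cells, the median difference of the list, lung minus liver, was -1.08 (SD 0.54 over members). In R276 and R312, whose lung cells had fewer, it was -0.86 (SD 0.42), and both values lay further than 1 SD below 0. These SDs also cover members, not animals. In each of these 4 animals 26 of 27 members were lower in lung. For R230 and R235 this argues against depth as the whole source. Their livers had high mitochondrial shares, so depth is not parted there from liver quality. Depth was near equal in R276, with a median of 3839 UMIs in liver and 3782 UMIs in lung, so the group with fewer rests mainly on R312. This test of depth took the place of one on cells with a UMI of MKI67 or TOP2A, each cell thinned to 1000 UMIs so that depth does not set the share. That share was lower in lung in 4 of 4 animals (-8.37 percentage points). Its bound, an exact permutation p of at most 0.05, was not met (0.119), so it does not decide on depth. In livers R276 and R312, 0.219% and 0.313% of barcodes had over 10% mitochondrial UMIs. The list medians of these animals were -0.77 (SD 0.37) and -1.02 (SD 0.60 over members). This argues against liver cell quality by that measure as the whole source in these animals, where organ and batch coincide. Quality together with batch, and a difference between the organs themselves, which the design names, may also be the cause and were not tested apart from these.

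A candidate explanation for many of the 413 genes higher in liver is the lower share of cycling cells in lung. With cells that had a UMI of MKI67 or TOP2A and the cycling clusters left out, edgeR called 0 of 11343 genes (978 at an unadjusted p under 0.05, DESeq2 not run on these sums), and the genes higher in lung lost their calls too, at a median of 0.63 (SD 0.37) over 180 genes. The median log2 fold change of the genes higher in liver went from -0.92 (SD 0.51, median SE 0.194) to -0.60 (SD 0.41, median SE 0.242), and that of the cell cycle list from -0.78 (SD 0.38) to -0.39 (SD 0.56), within 1 SD of 0. The first met the bound set before the test against the explanation, more than 1 SD below 0, but that bound took the removal as complete, while 49.5% of the median of the list was left. With the same share left the genes higher in liver would be at -0.45, against the -0.60 found, which is 65.0% of their median. The medians after the removal cover only genes still tested, 387 of the 413 and 25 of the 27 list members. Both shares left are therefore not over the same genes before and after. The SDs are over genes and do not measure the spread of a median, so they do not separate the -0.45 from the -0.60. As the removal was incomplete, a lower share of cycling cells and a difference within cells cannot be told apart here.

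No gene was called in the CD4 transcript class by edgeR (1316 at an unadjusted p under 0.05, 119 called by DESeq2), and the smaller number of cells is a possible explanation. With the CD8 class reduced in a single random draw to the cell numbers of the CD4 class, 200 genes were called. This is above the 15 set before the test as the bound against this explanation, so cell number alone did not account for it in this draw. Without liver R312 edgeR called 36 genes in the CD4 class. A larger spread between animals in the CD4 class stays open and was not tested.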
